A study of Drosophila melanogaster with 2 samples.

How the data were processed

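Chromatin from transgenic fly embryos (0 to 24 h, males and females together) was sheared by sonication to fragments of 200 to 800 bp and precipitated with an antibody against GFP, per the labels. The 2 libraries are biological replicates numbered 3 and 4 in the labels and form 1 group; no library of another condition was analysed here. No comparison between conditions, paired or not, could be made.

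The authors deposited 8 peak lists, 4 on each of the builds dm6 and dm3, and each was used. Per the texts deposited beside them, a relaxed list was made for each replicate and another for both together, each also derived from a further input that the control-normalized tracks share, and the IDR list was derived from these lists. That input is taken to be the control, which the texts do not state. The aligner, the peak caller, their versions, the IDR threshold and the read depth are not given in the sources used here, and the control was not analysed here. Each list gives a deposited signal per peak, the strength assigned by the peak caller, whose scale and normalization to depth are not stated. It also gives a deposited −log10 q-value, which ran from 2.03 to 3.24 in the dm6 IDR list and stood at its maximum for 869 of the 1445 peaks, so peaks were ranked by signal. The p-value column holds a placeholder throughout and was not used. All 1445 dm6 IDR peaks are in the pooled relaxed list with equal signals and are its 1445 strongest, and the same holds for the 1175 on dm3. Signals and ranks are the authors' own values and were not compared as amounts between lists; the correlation of replicates sets signals side by side, and the range of signals on each build is given as a description. The relaxed replicate lists hold 30000 peaks each, a fixed length that mixes peaks with background. Overlap between replicates used their strongest parts, while partners for the correlation, the comparison with weaker peaks and the background of genes with a relaxed peak used the lists more widely.

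Start sites, genes, exons and UTRs came from the Ensembl release 115 annotation of BDGP6.54, and sequence from the Release 6 assembly; all dm6 peaks on the 6 arms 2L, 2R, 3L, 3R, 4 and X end inside those arms. The annotation holds 23581 distinct start sites of 18164 genes on the arms after 5809 transposable element insertions were left out, a choice made after the annotation was read. Since no dm3 sequence or annotation was used here, dm3 lists were only counted, and no positions were converted between builds. Positions are 1-based.

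A summit within 500 bp of a start site counted as a start-site peak, and summits within 200 bp of each other as the same site. Shares have exact 95% binomial intervals, which cover counting error only. Beside a count of 0, the limit given is 3 counts of the total, which is lower than the upper end of the two-sided exact interval. Random expectation came from 1000 placements that kept the number of peaks per arm for start sites and 100 circular shifts for replicate overlap; medians and correlations have bootstrap intervals from 1000 draws; the difference in signal was tested with 100000 permutations. Arms were tested with exact binomial tests, gene lists and k-mers with Fisher's exact tests and known motifs with an exact sign test between each peak window of 201 bp and 1 flank chosen at random, each family with Benjamini-Hochberg adjustment and a threshold of 0.05. Motif tests had 1444 peaks with usable windows. For k-mers, those in at least 5 peak windows on 2L, 3L and X were screened, the leading 400 were ranked by Fisher's exact p, and the first 20 were tested on 2R, 3R and 4. All tests are two-sided. Peaks and genes are not independent replicates, so the p-values measure the spread over positions in this group, not over embryos.

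Genes were named by a rule set before the data were examined: CG15073; the 25 strongest start-site peaks that were among the 1445 strongest of both replicates, by the gene of the nearest start site; up to 4 members with the strongest peak from each gene list; the 5 strongest peaks over 1000 bp from a start site; and the 5 windows of 20 kb with most peaks. Of 322 symbols asked for in 12 lists given by name, 4 were not matched (Z4, calypso, nos and fc177). The lists share some genes, such as Abd-B.

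The statistics were tested on simulated data of the same size. Of 20 random peak sets, 1 gave p below 0.05 for the start-site share, and a simulated share of 49.3% was found as 49.3% (1445 peaks). Of 20 gene lists of 40 genes with 4-fold odds among 13945 genes, 9 were called, and of 20 unchanged lists 0. Of 19 motifs at random positions 0 were called, and a DREF element placed in 10% of the 1445 windows was found in 10.5%. An 8-mer placed in 8% of windows ranked 1, and 0 of 20 were called at random positions. A simulated overlap of 58.7% was found as 59.0%, a difference of 0.5 on the log2 scale as 0.56, a correlation of 0.9 as 0.898, and summits put 60 bp upstream as 60 bp upstream; 0 of 6 arms were called in peaks drawn by length. Shuffles kept every dinucleotide count in 200 of 200 windows. Peak windows were shuffled 100 times for the motifs and 8-mers, a check added after the results were seen: 10 of 19 motifs lay above the shuffled range, 8 within it and 1 below it.

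Alternatives covered the distance limits, protein-coding start sites alone, other backgrounds, the stronger 722 IDR peaks, merging of overlapping peaks, 7-mers, and each replicate left out (the 1445 strongest peaks of the other in place of the IDR list). The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.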

Results

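Binding of CG15073 in fly embryos was recorded by chromatin immunoprecipitation and sequencing (ChIP-seq), which recovers the DNA held by a chosen protein and lists the places where it piles up as peaks. The flies carried CG15073 with enhanced green fluorescent protein fused to its C-terminal end, and an antibody against GFP recovered the fusion protein from mixed-sex embryos aged 0 to 24 h. The series holds 1 group of 2 biological replicates, numbered 3 and 4 in the labels, and no second condition, so every comparison below is between positions, genes or replicates within that group. CG15073 (FBgn0034379) is a protein-coding gene at 2R:18705977-18708226 on the plus strand of dm6. It was placed among the genes of zinc finger proteins with a zinc-finger-associated domain (ZAD) before the data were examined.

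On the dm6 build, 1445 peaks were kept by the authors' irreproducible discovery rate (IDR) step and are called IDR peaks here. They are the 1445 strongest peaks of the list for both replicates pooled, and some ranked very differently in each replicate, such as that of tin (834 in replicate 3 and 18313 in replicate 4). Their deposited signal, a peak strength from the authors' peak caller with no stated scale, ran from 66.5 to 9689 with a median of 96.5. The relaxed lists made before that step held 23030 peaks for both replicates pooled and 30000 for each replicate alone. Read depth is unknown from these lists, so intervals cover the counting of peaks only.

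The strongest peak of all lay at HmgZ and HmgD, a neighbouring pair of genes for high mobility group box chromosomal proteins, with its summit at 2R:21703286 (peak 2R:21702762-21703927) and a pooled signal of 9689. It lay in introns of both genes, at −456 bp from the nearest HmgZ start site (negative values are upstream), and ranked 1 in replicate 3 (signal 6348) and 1 in replicate 4 (signal 3464). AIMP1, a component of the aminoacyl-tRNA synthetase complex, had the next strongest peak at a start site, with the summit at −19 bp (2R:8928124), a signal of 4737 and a start site of PAN2 also within 500 bp. It was followed by Rac2 (3L:7435403, signal 4318), and SP1173 (3L:6703617, signal 3616). Peaks of these 4 genes ranked between 1 and 6 in both replicate lists.

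Among the 458 peaks within 500 bp of a protein-coding start site that were also among the 1445 strongest of both replicates, the 25 strongest had signals from 583 to 9689 and named 25 different genes. Dfd, a homeotic gene of the head segments, had its summit at −316 bp (3R:6791520, signal 2000), between genes. SdhD, a subunit of succinate dehydrogenase, had its summit at −37 bp (3R:23760637, signal 1367). The peak at Rlb1 (3R:9513308, signal 1307) also lay within 500 bp of a start site of Ras85D, the fly Ras gene. The gene mtd had 2 of the 25 peaks. The stronger lay in the 5' UTR of the first exon of a transcript that starts inside the gene (3R:5282930, signal 1301). The weaker lay in an intron (3R:5287495, signal 616). Further peaks lay at RhoGAP68F (3L:12139282, signal 1080) and at Cortactin, an actin-binding protein (3R:21064553, signal 840). Others lay at kuk, which encodes a nuclear envelope protein (3R:17080735, signal 1074), and at the eye colour gene car, which encodes a vesicle-sorting protein (X:19566179, signal 1003). Peaks of this set were also found at the kinase gene fray (3R:18585759, signal 981) and at Sox102F, a Sox-family transcription factor gene (4:834366, signal 914). The remaining members were Faf2, CG6023, galectin, CG44000 with CG44001, Adk2, CG14100, Ugalt, vir-1, S6KL and CG7739.

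**Figure D1:**
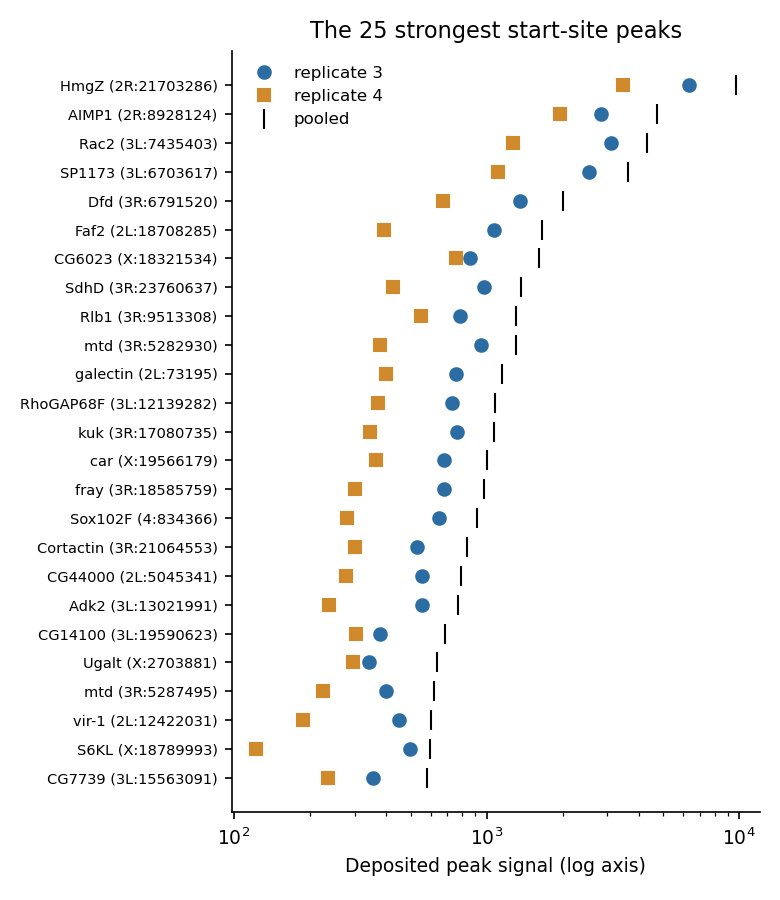
Deposited peak signal (log axis) of the 25 strongest start-site peaks in replicate 3 (circles), replicate 4 (squares) and the pooled list (bars), each row a peak with its gene and dm6 summit. HmgZ is at the top with 6348 in replicate 3 and 3464 in replicate 4, and CG7739 at the bottom has a pooled signal of 583.

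Strong binding was also found away from start sites. The second strongest peak in the list lay between genes, at −1468 bp from Jhbp2 (3R:4962819, signal 6779, rank 2 in both replicates). Of the other peaks over 1000 bp from any start site, the strongest lay in introns of psq, a BTB-domain transcription factor gene (2R:10564235, signal 2570), of trbl, a pseudokinase gene (3L:20399771, signal 1827), and of fray (3R:18574153, signal 1049). The last of the 5 lay in an intron of brat, a translational repressor gene, at −2092 bp from lncRNA:CR44977 (2L:19161391, signal 928).

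Peaks crowded together most on the X chromosome. The 20 kb window with most peaks held 9 within 10334 bp at Raf, the kinase gene of the Ras pathway (X:2293706-2304039), and 1 of them lay within 500 bp of a start site. It was followed by 8 peaks at CG4004 and Smr, a co-repressor gene (X:12734946-12754566), 7 at CG1677 (X:7292032-7307191) and 7 at the forkhead gene CHES-1-like (X:7697024-7709108). The fifth window held 6 peaks at CG4297, MED15, cbt and ush, the last a cofactor gene of GATA factors (2L:470099-485841). The tagged gene itself had no peak within its borders or 500 bp around them in the IDR, pooled or either replicate list. The nearest IDR summit lay 34267 bp away.

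The replicates were compared to see how far the same sites recurred. Within 200 bp of the IDR summits, 83.2% (1202 of 1445; exact 95% interval 81.2 to 85.1) had a summit among the 1445 strongest peaks of replicate 3 and 75.8% (1096; 73.6 to 78.0) among those of replicate 4. Both conditions held for 62.9% (909; 60.4 to 65.4), against a mean of 0.224% and a maximum of 0.484% over 100 circular shifts of the summits along their arms. HmgZ and Jhbp2 kept ranks 1 and 2 in both lists, whereas the peak of S6KL ranked 43 in replicate 3 and 113 in replicate 4. Across the 1384 IDR peaks with a partner in both lists, Spearman's rho of the replicate signals was 0.604 (95% bootstrap interval 0.559 to 0.643) and Pearson's r of log2 signals 0.811. Peaks are not independent replicates, and the IDR peaks are the strongest of the pooled list, so these values describe the lists and no p-value is given. The recurrence depended on the distance allowed and on the depth of the list: it was 44.6% within 50 bp, 84.7% among 2 times as many replicate peaks and 92.9% for the stronger 722 IDR peaks.

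**Figure D2:**
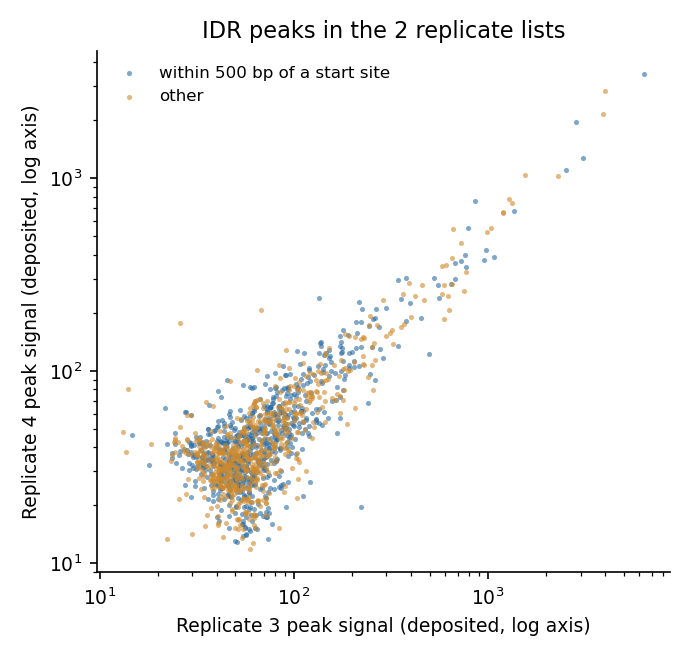
Deposited signal of the peak nearest to each IDR summit in replicate 3 (horizontal, log axis) and replicate 4 (vertical, log axis) for 1384 IDR peaks, coloured by distance to a start site. The points form a single band that narrows towards the strongest peaks (Spearman's rho 0.604).

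The next comparison asked where in genes the fusion protein was found. Start sites stood out: 52.4% of summits (757 of 1445; exact 95% interval 49.8 to 55.0) lay within 500 bp of the start of an annotated transcript, against 13.6% on average and at most 17.6% in 1000 random placements. Since the shares of all classes add up to 100%, the other classes were compared among the 688 summits outside start sites, a comparison chosen after the shares were seen. Introns held 66.6% of these (exact 95% interval 62.9 to 70.1; random 45.6%), intergenic sequence 25.1% (21.9 to 28.6; random 31.3%), coding sequence 3.05% (1.90 to 4.63; random 16.2%) and 3' UTRs 2.03% (1.12 to 3.39; random 5.15%). The two-sided permutation p for start sites was 0.002, the smallest that 1000 placements can give. Of the replicate peaks ranked below the median signal of their list, 16.5% lay at start sites (4964 of 29998; Fisher's exact test against the IDR peaks, two-sided, p = 2.07e-200). For the 709 summits within 500 bp of a protein-coding start site, the median position was −140 bp (95% bootstrap interval −155 to −132) and 85.3% lay upstream.

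**Figure D3:**
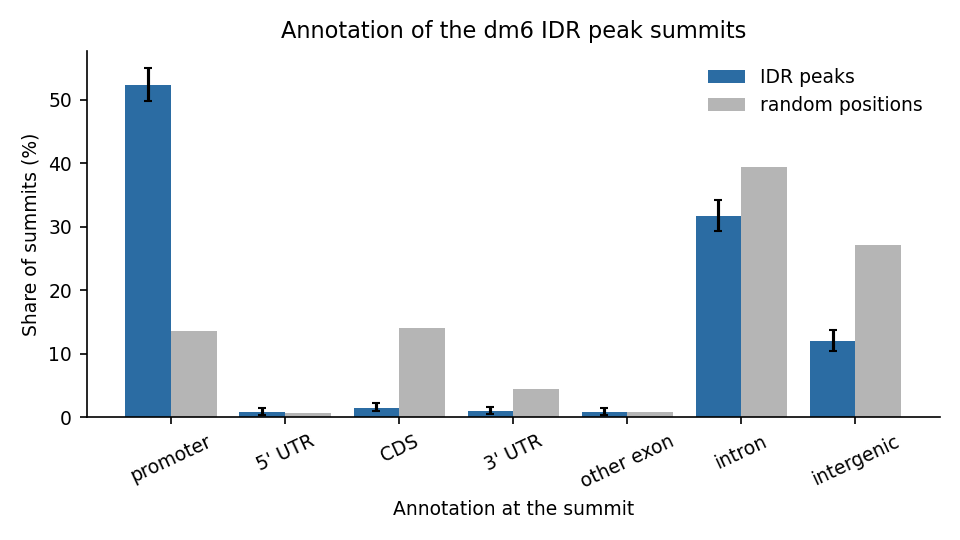
Share of the 1445 IDR summits (blue, with exact 95% intervals) and of random positions on the same arms (grey) in each annotation class, where promoter means within 500 bp of a start site. Promoters hold 52.4% of summits against 13.6% of random positions, and coding sequence holds 1.45%, or 0.104 times its random share.

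Peaks at start sites had a slightly higher signal than others, with medians of 99.2 (n = 757 peaks) and 92.4 (n = 688 peaks). The difference of medians was 0.10 on the log2 scale (95% bootstrap interval 0.03 to 0.17; two-sided permutation p = 0.00847). Among the strongest 1445 peaks of replicate 3 alone it was 0.035 (two-sided permutation p = 0.384), so the difference did not hold without replicate 4.

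Chromosome arm 2R carried fewer IDR peaks than its share of protein-coding start sites. It held 17.4% of peaks (exact 95% interval 15.5 to 19.4) against 20.5% of start sites (exact binomial test, two-sided, p = 0.00332, adjusted p = 0.0199 over the 6 arms). The X chromosome held 19.0% against 17.0% and did not pass (exact binomial p = 0.0499, adjusted p = 0.149), and neither did 2L, 3L, 3R or 4. The 2R call was lost against the share of assembled length (18.9%; adjusted p = 0.222, exact binomial test) and in the stronger 722 peaks (adjusted p = 0.344, exact binomial test). Against length, 2L passed instead, with 20.7% of peaks on 17.6% of the sequence (adjusted p = 0.0125, exact binomial test).

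Of 13945 protein-coding genes, 941 (6.75%) had an IDR summit within 500 bp of a start site. The lists of genes fixed before the data were examined were compared with all other genes by Fisher's exact test, two-sided, adjusted over 19 lists. Chemoreceptor genes, the odorant, gustatory and ionotropic receptors, had a peak at 0 of 179 genes, which allows up to 1.68% (exact two-sided 95% interval up to 2.04%), against 6.84% of other genes (Fisher's exact test, adjusted p = 0.000125). Of 49 chemoreceptor genes with a peak in a relaxed replicate list, 0 had an IDR peak against 12.6% of other genes with such a peak (Fisher's exact test, adjusted p = 0.0325). Transfer RNA genes had peaks at 2 of 290 (0.69%), tRNA:Tyr-GTA-1-8 and tRNA:Gln-TTG-2-1, against 5.76% of all other genes (Fisher's exact test, adjusted p = 0.000145). Those other genes are mostly protein-coding (13945 of all 18164 genes). Other non-coding genes were low too, with peaks at 3 of 269 small nucleolar RNA genes (1.12%) and 85 of 3261 ncRNA genes (2.61%). The low share was thus not particular to transfer RNA genes, and these classes were not tested against each other. The odds ratio of transfer RNA genes, 0.114, became 0.297 without replicate 4 (5 of 290; Fisher's exact adjusted p = 0.0111) and 0.0621 without replicate 3 (1 of 290; Fisher's exact adjusted p = 0.000114). Replication-dependent histone genes had a peak at 0 of 111, which allows up to 2.70%, against 6.80% (Fisher's exact test, adjusted p = 0.00537). None of those histone genes had a peak in either relaxed replicate list, whereas all 941 protein-coding genes with an IDR peak had one. A count of 0 was thus settled before the test. Fisher's exact test also counts repeated copies as separate genes, so its p-value and the limit overstate what was learned. Histone and transfer RNA genes are repeated in the genome, and mappability was not analysed here. Of 163 transfer RNA genes with a relaxed replicate peak, 2 had an IDR peak (1.23%). Other genes with such a peak had one in 11.3% (Fisher's exact test, adjusted p = 3.36e-05). Peaks could be called near those 163, which argues against a complete lack of mappable reads there but not against a partial one. The histone call was lost in the stronger 722 peaks (adjusted p = 0.23, Fisher's exact test).

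No list was bound more often than other genes at an adjusted p below 0.05. Cell cycle genes had peaks at 6 of 42 (14.3%, exact 95% interval 5.43 to 28.5; Fisher's exact adjusted p = 0.29), the strongest at CycE (signal 94.5), RnrS (88.8), dpa (86.8) and dup (77.2), genes of S-phase entry and DNA replication. This fell to 3 of 42 without replicate 4 and 0 of 42 in the stronger 722 peaks. Homeotic genes had 2 of 8, Dfd (signal 2000) and Abd-B (95.6), with a Fisher's exact adjusted p of 0.369. Ribosomal protein genes had 9 of 86 (adjusted p = 0.592, Fisher's exact test), the strongest at RpL34b (128.02), RpS27 (123.6), RpL7 (120.5) and RpL32 (99.2). For the lists that follow, Fisher's exact adjusted p lay between 0.592 and 1. Heat shock genes had 3 of 24, Hsp27 (190.6), Hsc70-5 (99.4) and Hsp26 (76.6). Respiratory chain genes had 5 of 86, led by SdhD (1367), ND-B17 (316), ND-ASHI (134) and ND-MWFE (116), and proteasome genes 3 of 44, Rpn3 (92.1), Rpn5 (81.2) and Rpt5 (69.8). Polycomb and trithorax group genes had 3 of 29, ph-p (405), brm (166) and E(z) (102), and insulator protein genes 2 of 20, Chro (441) and Cp190 (149). Muscle genes had 3 of 29, Msp300 (136), sls (102) and Tm1 (81.1).

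The other lists did not pass either, with Fisher's exact adjusted p between 0.616 and 1. Early patterning genes had 2 of 36, bcd (signal 102.9) and tin (77.5), and neural genes 2 of 32, elav (180.9) and moody (126). Germline and piRNA genes had 2 of 29, Sxl (319) and piwi (78.2), gut, fat body and blood genes 2 of 29, Abd-B and fkh (68.4), and ZAD zinc finger genes 2 of 21, pad (82.9) and Sry-delta (67.5). Eggshell genes had 0 of 17 and small nuclear RNA genes 0 of 32, which allow up to 17.6% and 9.38%. In simulated data 9 of 20 lists of 40 genes with odds raised 4-fold were called, so differences of that size or smaller would often be missed. Many lists tested here held fewer than 40 genes, a size that was not simulated.

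Sequence motifs were searched within 100 bp of the summits and compared with windows of the same peaks centred 1000 bp to each side, by an exact sign test adjusted over 19 motifs. The CTCF core AGRKGGCGC was in 2.77% of peaks (40 of 1444; exact 95% interval 1.99 to 3.75) and 0.242% of flanks (adjusted p = 3.24e-07), and it passed under every alternative run. The homeodomain core TAATTA was in 16.6% of peaks and 11.1% of flanks (exact sign test, adjusted p = 3.37e-06), but its share lay within the range of 100 shuffles of the peak windows (16.1% to 21.5%), so the excess over flanks was not separated from base composition. It was in 15.0% and 11.6% without replicate 4 (exact sign test, adjusted p = 0.167) and in 15.4% and 11.0% for the stronger 722 peaks (exact sign test, adjusted p = 0.0927), similar shares that did not pass. Ohler motif 7 was in 6.51% and 3.88% (exact sign test, adjusted p = 0.023) and the DREF element TATCGATA in 1.32% and 0.485% (exact sign test, adjusted p = 0.0281). Ohler motif 7 kept most of the difference without replicate 3 (5.68% and 3.81%) but did not pass (exact sign test, adjusted p = 0.104). Without replicate 4 the DREF element fell to 1.04% and 0.623% (exact sign test, adjusted p = 0.504). The Tramtrack site CAGGACC was lower, in 0.139% of peaks (2 peaks) and 1.11% of flanks (exact sign test, adjusted p = 0.0281), and stayed lower without replicate 3 (0.277% and 1.04%; exact sign test, adjusted p = 0.116) without passing. The other 14 motifs passed in neither direction (exact sign test, adjusted p from 0.0528 to 1). Of sites for DNA-binding factors, Su(Hw) was in 1.73% of peaks and 0.623% of flanks, Pho in 29.7% and 32.9%, GATA in 7.41% and 6.48%, GAGA in 4.22% and 4.09%, Zelda in 1.25% and 1.56%, Twist in 2.35% and 2.15%, BEAF-32 in 23.1% and 22.3% and the heat shock element in 0.346% and 0.208%. Of core promoter motifs, TATA was in 3.81% and 2.46%, Initiator in 16.9% and 17.1%, Ohler motif 1 (M1BP) in 0.762% and 0.381%, motif 5 in 1.04% and 0.589%, motif 6 in 0.416% and 0.173% and motif 8 in 0.623% and 0.866%. Against 1445 start sites of genes with no IDR peak within 2 kb, the DREF element was in fewer peaks (1.31% against 6.09%, Fisher's exact adjusted p = 2.3e-11) and so was Ohler motif 7 (6.51% against 9.34%, Fisher's exact adjusted p = 0.00997), as was Initiator (16.9% against 31.9%, Fisher's exact adjusted p = 9.04e-20), while Su(Hw) was higher (1.73% against 0.346%, Fisher's exact adjusted p = 0.000721). Those windows were centred on start sites and most peak windows were not. Fewer core promoter motifs and more Su(Hw) sites in peaks may thus come from how the windows were placed, which was not tested.

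An open search for 8-mers chose the 20 most enriched in peaks on 2L, 3L and X and tested them in peaks on 2R, 3R and 4. There, 19 of the 20 were more frequent at summits than in flanks (Fisher's exact test, adjusted p below 0.05 in the held-out arms). CACAGTGG was in 8.82% of 601 held-out peaks and 2.16% of flanks (Fisher's exact adjusted p = 4.34e-09) and ACAGTGGC in 6.16% and 0.915% (Fisher's exact adjusted p = 4.34e-09). The 8-mers held ACAGTG in 6 cases. Some were neither such words nor runs of A and T. Among these were ACAGTCGC (3.83% against 0.666%, Fisher's exact adjusted p = 8.01e-06) and TACACTGA (3.33% against 0.499%, Fisher's exact adjusted p = 1.15e-05). Others were runs of A and T such as ATATTTTA (9.98% against 3.16%, Fisher's exact adjusted p = 4.97e-08). Peak windows held less G and C than flanks (36.7% against 43.2%), which favours such words. In 100 shuffles of the held-out windows that kept dinucleotide counts, chosen as a check after the 8-mers were seen, every shuffle gave a lower share than observed for 16 of the 20, ATATTTTA among them (at most 6.99%). The 4 that did not were ATATTAAA, ATTTTTAA, AAATTTAA and AAATATTA. The only one not to pass was CAGTGTAG (1.33% against 0.499%, Fisher's exact adjusted p = 0.0839).

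The 6-mer with the lowest p on 2L, 3L and X was also ACAGTG, a length chosen after the 8-mers were seen on all arms, so 2R, 3R and 4 are not a blind test of it. On 2R, 3R and 4 it was in 27.0% of peaks (162 of 601) and 8.99% of flanks (Fisher's exact p = 1.55e-22). It lay within 100 bp of the summits at HmgZ, Jhbp2, AIMP1 and Rac2, but not at SP1173, Dfd or SdhD, and at 14 of the 25 strongest start-site peaks. In the pooled list, with rank limits set after the data were seen, 59.6% of the held-out peaks ranked 1 to 100 held it (28 of 47; exact 95% interval 44.3 to 73.6), 24.0% of those among the next 200, 23.8% of those ranked 701 to 1445 and 8.09% of those ranked below 12000. The share of peaks near start sites was 49% for ranks 1 to 100, 57% for the next 200 peaks and 16.2% at the end of the list.

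**Figure D4:**
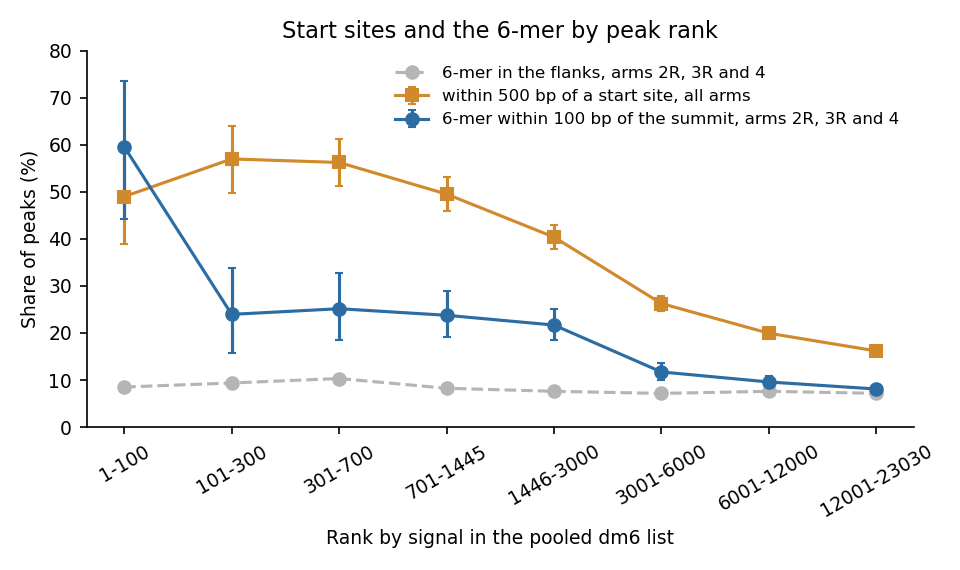
Share of pooled dm6 peaks by signal rank that lay within 500 bp of a start site (squares, all arms) or held ACAGTG within 100 bp of the summit (blue circles, arms 2R, 3R and 4), with exact 95% intervals, and the share of flank windows with ACAGTG (grey). The 6-mer falls from 59.6% at ranks 1 to 100 to 24.0% in the next 200 peaks, while start sites go from 49% to 57%.

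**Figure D5:**
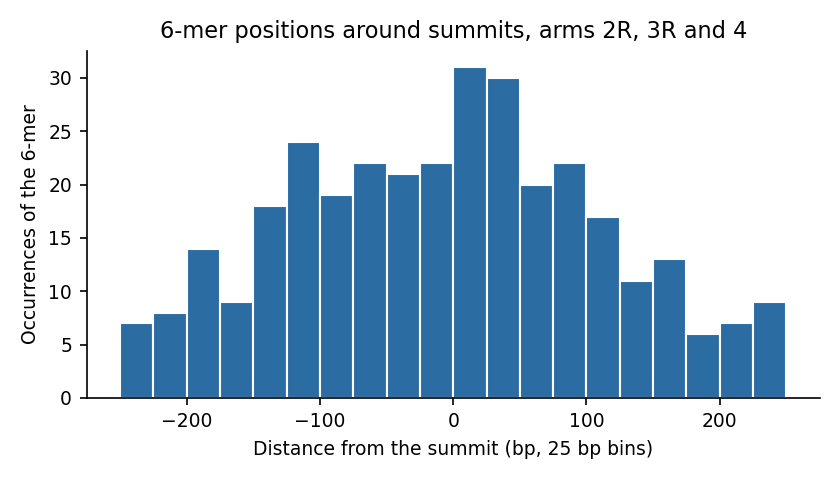
Occurrences of ACAGTG or its reverse complement in 25 bp bins by distance from the summit, held-out peaks on 2R, 3R and 4. The bins from 0 to 49 bp hold 31 and 30 occurrences, the other bins within 100 bp 19 to 22, and the outermost bins 7 and 9.

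The same libraries were also called on the older dm3 build, where 1175 peaks passed IDR with a median signal of 109 and a maximum of 9665. The dm6 list was 1.23 times as long, and longer on every arm, with 1.18 times as many peaks on 3L and 9 against 6 on chromosome 4. The weakest peak kept had a signal of 73.7 on dm3 and 66.5 on dm6. Named genes were not compared between the builds, since positions were not converted.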

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

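The tests of the peaks off the arms were chosen after the result was seen. On dm3, 927 of the 30000 peaks of replicate 4 (3.09%, exact 95% interval 2.90 to 3.29) and 125 of the 30000 of replicate 3 (0.417%, 0.347 to 0.496) lay on sequences other than the arms 2L, 2R, 3L, 3R, 4 and X, which no comparison in the results used. The dm3 IDR list held none among 1175, which allows up to 0.255% (exact two-sided 95% interval up to 0.313%). On dm6, replicate 3 had 1 of 30000 peaks off the arms and replicate 4 had 2, all on the Y chromosome. The larger number in replicate 4 was thus seen in the dm3 lists only.

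A candidate explanation is that these are weak calls in a list of fixed length. Among the 1175 strongest peaks of replicate 4, 0.340% lay off the arms (4 peaks, exact 95% interval 0.0928 to 0.869). This was a lower share than among the other 28825 (Fisher's exact p = 1.1e-11), as weak calls would give. Among the 1175 strongest of replicate 3 there were 0. The strongest of them in replicate 4 ranked 602. Their median rank was 16236 of 30000 in replicate 4, near the middle of the list, and 20261 in replicate 3. In replicate 4 they were thus scarce among the strongest peaks but not gathered at the weak end. Both lists have the same length, so a fixed length alone does not account for the larger number in replicate 4. Why replicate 4 has more of them than replicate 3 on dm3 stays open, since depth and the mapping of repeats are not given in the sources used here. No biological explanation was tested, because the design has 1 group.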

How the results depend on the processing

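The alternatives with dm3 lists (1175 IDR peaks, 65.3% recurrence) and with transposable element insertions kept (start-site share 52.8%) were chosen after the data were seen. The start-site share stayed above its comparison under all 9 alternatives (37.3% within 250 bp to 63.8% within 1000 bp; 47.2% and 52.2% with a replicate left out), the upstream position stayed between −145.5 and −134 bp, 17 to 20 of the 20 k-mers passed, and 2 or 3 gene lists were called in each setting, with chemoreceptor and transfer RNA genes lower in all 6. With the stronger 722 IDR peaks the recurrence was 92.9% and rho 0.67, the 2R share 18.1% no longer passed, 1 motif was enriched, histone genes kept an odds ratio of 0 without passing, and the log2 ratio of the DREF element was −0.15. Recurrence was 44.6% within 50 bp and 84.7% among 2 times as many replicate peaks. Against assembled length, 2R (17.4%) no longer passed and 2L (20.7%) did. The start-site signal difference ranged from 0.035 without replicate 4, no longer past the threshold, to 0.21 without replicate 3. Enriched motifs numbered 2 within 50 bp, where the log2 ratio was −0.048 for Ohler motif 7 and −1.07 for GAGA, and 8 within 250 bp, where GAGA passed in the other direction (0.92). The homeodomain core, Ohler motif 7, the DREF element and the Tramtrack site did not pass in the stronger 722 peaks, and the last 3 did not within 50 bp. Su(Hw) and Ohler motif 5, which did not pass in the IDR peaks, passed with either replicate left out (log2 ratios 1.23 to 1.69 and 1.27 to 1.77). With unbound start sites as background, log2 ratios were −2.18 for the DREF element, −0.71 for the BEAF-32 core, −2.11 for Ohler motif 1, −1.52 for Ohler motif 5, −1.73 for Ohler motif 6, −0.52 for Ohler motif 7 and −0.78 for TATA, all opposite in sign to those against flanks; Initiator (−0.92) and Su(Hw) (2.21) passed there but not against flanks of the IDR peaks. That background is centred on start sites. Core promoter motifs may be more frequent in it, and Su(Hw) sites less frequent, because of that placement, which was not tested. Values that passed under neither setting were given no direction; their sign differed in 27 of 96 cases for lists, 16 of 66 for motifs and 6 of 24 for arms. The odds ratio of histone genes has no value among genes with a relaxed peak, since none has such a peak. The cause of the other shifts was not tested. No paired analysis was possible because the series has 1 group. Depth is unknown, so its effect on weak peaks cannot be judged.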

Other observations

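All tests in this part were chosen after the peaks were seen. The 40 IDR peaks with the CTCF core, an insulator protein's site, were singled out after the motif test. The strongest lay at −594 bp from wgn (negative values are upstream), a tumour necrosis factor receptor gene (X:18635502, signal 1027), in an intron of HmgZ at −606 bp from HmgD (2R:21700852, signal 730) and in the 3' UTR of para, the voltage-gated sodium channel gene (X:16458780, signal 664). Further ones lay at −115 bp from SLIRP2 (3R:8650969, signal 285), in coding sequence of otp, a homeobox gene (2R:20884582, signal 240), and at −1519 bp from Men, the malic enzyme gene (3R:12723961, signal 239). Of the 40, 35% lay within 500 bp of a start site against 52.9% of the other 1405 (Fisher's exact p = 0.0357, unadjusted, 1 of 3 comparisons). They held ACAGTG in 30% against 25.6% (Fisher's exact p = 0.582) and recurred in both replicates in 62.5% against 62.9% (Fisher's exact p = 1).

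The peak of Faf2 on 2L held 2 summits, at 18708073 in an intron (signal 3159) and at 18708285 in the 5' UTR (signal 1653), and the first of these had ACAGTG nearby. Among the 12 strongest peaks, those at Caper, a splicing-related gene (2L:7033489, signal 2061), and Ih, an ion channel gene (2R:14275519, signal 2035), lay at 768 and −611 bp from a start site and so fell between the classes of the results.

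A hypothesis is that ACAGTG is part of a sequence that CG15073, or a protein recovered with it, recognises. Base composition alone is argued against: over 100 shuffles of the held-out windows that kept dinucleotide counts, the highest share was 10.6%, below the observed 27.0% (exact 95% interval 23.4 to 30.7), although peak windows had 36.7% G and C against 43.2% in flanks. The sequence of start sites in general is argued against as well, since 32.5% of the 265 held-out peaks over 500 bp from a start site held the 6-mer (26.9 to 38.5) against 9.06% of their flanks (Fisher's exact p = 1.04e-15), and unbound start sites held it in 9.51%. Occurrences within 25 bp of the summit were 1.56 times an even spread over 250 bp to each side (53 of 330, exact binomial p = 0.00106). The 6-mer was already known to be more frequent within 100 bp of these summits, so this test largely repeats that result. Within 100 bp, the bins of 25 bp from 0 to 49 bp held 31 and 30 occurrences and the others 19 to 22. Centring within those 100 bp was not tested. Recovery of another factor that shares these sites stays open, since no control precipitation was analysed here, and the held-out arms had been looked at before these tests were chosen.

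A hypothesis for the share of peaks at start sites is that it does not come from ACAGTG. Held-out peaks without the 6-mer lay at start sites in 59.2% (n = 439, exact 95% interval 54.5 to 63.9) and those with it in 46.9% (n = 162, 39.0 to 54.9; Fisher's exact p = 0.00737), each above the highest of 1000 random placements of as many peaks on the same arms, 19.4% and 24.7%. This argues against the 6-mer lying at start sites as the whole cause. Unspecific recovery of highly transcribed promoters could also raise the share: ribosomal protein, proteasome and respiratory chain genes had a peak at 17 of 216 genes (7.87%) against 6.73% of others, an odds ratio of 1.18 (95% interval 0.673 to 1.95; Fisher's exact p = 0.493). That interval includes both no excess and a moderate one, so this explanation cannot be told apart from specific recruitment by these data. The share was 10.5% for ribosomal protein genes, 6.82% for proteasome genes and 5.81% for respiratory chain genes. In the relaxed replicate lists, which mix peaks with background, 76 of 86 ribosomal protein genes had a peak against 7468 of 13859 other genes. Proteasome genes had such a peak at 22 of 44 and respiratory chain genes at 54 of 86, which was not tested.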
